A study of Mus musculus with 4 samples.

How the data were processed

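Chromatin immunoprecipitation with sequencing (ChIP-seq) was done in cardiac fibroblasts of newborn mice, per the labels. Cells carrying a TEAD1 overexpression construct (OE-TEAD1) and cells carrying its negative control (OE-NC) each gave 1 ChIP library and 1 input library, so the 4 groups held 1 library each and there were no replicates. Input is sonicated chromatin set aside before the immunoprecipitation. It measures how much DNA each part of the genome contributes without an antibody. Chromatin was crosslinked with formaldehyde and sonicated, per the labels' protocols, and the antibody is not given in the sources used here.

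Reads were trimmed with Trimmomatic 0.33 and aligned with Bowtie 1.1.2, and peaks were called with MACS2, per the submitters' processing notes. The MACS2 version, its settings and any removal of duplicate reads are not given in the sources used here. The files used were 2 deposited peak lists, each called against input, without a header. The labels do not tie either list to OE-NC or OE-TEAD1, and no value in the lists was used to guess it. They are called list 1 and list 2, and no direction between the conditions was drawn. Each list comes from 1 calling against input, and nothing in the labels speaks of pooled libraries.

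For each peak the deposited lists give a start, an end and a summit, and a score that equals the whole part of 10 times the −log10 q in the authors' list. The deposited fold is the ratio of the ChIP pileup at the summit to the local background that MACS2 takes from the input, with 1 added to both. The authors' −log10 p and −log10 q of each peak come from a Poisson test of that pileup against that background. The fold, p and q are the authors' values of single peaks. They were used to describe, rank and filter peaks within a list, and folds of shared sites were set side by side without a test.

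The notes name the build as mm39, but peaks run past the ends of chromosomes 2, 3, 7 and X of that build. As a check, summits were counted within 1 kb of an end of a protein-coding gene of the GRCm38.p6 RefSeq gene table, as they stood and after 100 shifts of 20 to 118 kb. The unshifted counts were 1129 in list 1 and 1072 in list 2, against medians of 891.5 and 873.5 and highest counts of 943 and 972 after shifting. Coordinates were therefore read as GRCm38, and they are given as in the lists, counted from 1. No coordinate was converted.

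The gene table gives the span of each gene without strand, exons or sequence. Distances to transcription starts were planned before the data were examined and were replaced by distances to either end of the gene's annotated span. This adds the 3′ ends of genes to every count of nearby peaks. Whether a peak lay in an exon, an intron or an untranslated region was not analysed here. Tests of the TEAD binding motif at summits, in all peaks and in shared against list-only peaks, needed a genome sequence and were not run.

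The lists held 21285 and 21218 peaks, all on chromosomes 1 to 19 and X, and no interval occurred more than once. Library sizes are not in the lists. The depth behind each peak was recovered by solving the deposited fold and p for the number of ChIP fragments at the summit and the local background. The fragment number came out whole, within 0.02, for 99.99% of peaks in each list, all but 2. The lowest background in a list, its genome-wide floor, was 1.72 fragments in list 1 and 1.87 in list 2. Exact Poisson 95% intervals of the fragment number gave the intervals of the folds. These intervals cover counting error in the ChIP library only, not the error of the input or between cultures. The lowest number of fragments at a summit was 8 in both lists.

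Peaks were shared when they overlapped by at least 1 bp. The shared percentage was compared with 100 random placements of the other list's peaks between the first and the last peak of each chromosome (one-sided permutation p). Assembly gaps were not excluded from the placements. Pairs that were each other's best overlap entered the comparison of folds. Percentages of peaks have Wilson 95% intervals. Peak positions were compared with 200000 random positions, distributed over chromosomes like the peaks, by two-sided Fisher's exact tests.

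A gene had a nearby peak when a summit lay within 10 kb of either end of its span. Before the data were examined 16 gene lists were fixed from general knowledge, with 352 members, all of which matched a symbol in the gene table. They covered YAP/TEAD targets, Hippo pathway components, activated fibroblast genes, other extracellular matrix genes, TGF-beta and BMP signalling, Wnt signalling, AP-1 and immediate-early genes, actin cytoskeleton and adhesion genes, and resident fibroblast markers. Markers of cardiomyocytes, endothelium, leukocytes, smooth muscle and pericytes, and epicardium, cell cycle genes and neuronal genes completed them. Each list was compared with all other protein-coding genes (21883 in all) by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 32 tests and a threshold of 0.05. In every odds ratio 0.5 was added to each cell, so that with 0 members near a peak this addition sets the ratio. Percentages of members have exact Clopper-Pearson 95% intervals. Members with a peak in only one list were compared by an exact McNemar test. Genes are not independent replicates, and these tests describe the peaks of 1 ChIP library each, not the conditions.

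Named genes followed a rule fixed before the data were examined. It took the 10 protein-coding genes per peak list with the highest −log10 q within 10 kb. It also took up to 3 members per gene list, ranked by the lower of their −log10 q in the peak lists, and the 5 list-only peaks with the highest −log10 q per peak list. Tead1, Ccn1, Ccn2, Ankrd1, Wnt4, Acta2, Postn and Col1a1 were always included. Some genes that the rule takes are not reported here. Genes outside the rule were chosen after their values were seen. They are marked so, share a peak with a named gene, or are named in the additional observations.

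Alternatives planned beforehand were a −log10 q of at least 5, the 5000 peaks per list with the highest −log10 q, rows as deposited, other sequences, stricter overlap (50% of both peaks, or summits within 100 bp), other distances and gene sets, and a binomial test over base pairs. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The steps were tested on simulated data. Fragment numbers were recovered for 100% of 5000 simulated peaks. With 25% of 21218 placed peaks put on list 1 peaks, 25.7% were counted as overlapping. Of 200 random lists of 22 genes 2.5% fell below 0.05 unadjusted, and of 200 lists drawn with 7 to 1 odds for genes with a list 1 peak 98.5% did.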

Results

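TEAD1 is a DNA-binding partner of the Hippo pathway coactivators YAP and TAZ, and the study asked which regulatory elements it binds in cardiac fibroblasts of newborn mice. ChIP-seq was done once in cells overexpressing TEAD1 and once in control cells, each with its own input, which made 4 libraries in 4 groups. The deposited data were 2 lists of peaks called against input. Neither list is tied to a condition by its labels, so they are described as list 1 and list 2 and no effect of overexpression is given. There were no replicates. Fold over input, p and q are the authors' values, and all coordinates are GRCm38.

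List 1 held 21285 peaks and list 2 held 21218. Their median widths were 472 and 445 bp, and the median fold over input was 6.24 in list 1 and 6.83 in list 2. A fold of at least 10 was reached by 4880 peaks in list 1 and 5955 in list 2. The median peak rested on 19 ChIP fragments at its summit in list 1 (quartiles 14 and 30) and on 22 in list 2 (quartiles 15 and 35). The smallest −log10 q was 1.349 in list 1 and 1.302 in list 2. A weak peak therefore had a wide counting interval: the Tead1 peak of list 2, with 15 fragments, was 5.58-fold over input (95% interval 3.28 to 8.98).

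The strongest peaks near genes lay at the same sites in both lists. The highest −log10 q within 10 kb of an end of a protein-coding gene belonged to a set of sites that included 2610008E11Rik (53.8-fold in list 1 and 117.5-fold in list 2), Epdr1 (60.4-fold and 108.9-fold, 0.45 kb from a gene end), Fam107b (70.5-fold and 97.3-fold) and Gm52140 (47.9-fold and 77.7-fold). The 2610008E11Rik, Fam107b and Gm52140 sites lay 8.9, 7.8 and 6.4 kb from a gene end. One summit lay near both Zfp672 and Sh3bp5l and was 61.8-fold and 79.7-fold over input. Gpr65, Lclat1, Cx3cl1, encoding the chemokine fractalkine, and S100a11 ranked among the first 10 in list 1, with folds of 64.2, 66.5, 68.3 and 41.0. In list 2 the first 10 included a summit shared by Tfrc, the transferrin receptor, and Tnk2 (102.9-fold). Pdgfc, encoding a platelet-derived growth factor (97.3-fold, 7.81 kb from a gene end), and Ddi1 (47.5-fold) were also among them. The Ddi1 site had 663 fragments in list 2 and 163 in list 1 and lay in a block of chromosome 9 with raised input background. It also lay inside the span of Pdgfd, 101.7 kb from an end of that gene.

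Peaks were found across genes and between them, with an excess near genes. Of list 1 peaks 48.4% had their summit inside a protein-coding gene span, against 40.8% of random positions (odds ratio 1.36, 95% interval 1.32 to 1.40, Fisher p = 3.82e-99). List 2 had 47.7% against 40.8% (odds ratio 1.33, Fisher p = 4.89e-85). Within 1 kb of a gene end lay 5.30% of list 1 peaks (Wilson interval 5.01 to 5.61) against 3.03% of random positions, and 5.05% of list 2 peaks (4.77 to 5.36) against 3.18%. The odds ratios were 1.79 (exact p = 4.56e-61) and 1.62 (exact p = 1.53e-41). The median summit lay 25.3 kb from an end of a protein-coding gene in list 1 and 26.4 kb in list 2. These distances run to the outer ends of gene spans, also for summits inside a gene, and their medians were not compared with random positions. Peaks outside gene spans and over 10 kb from an end made up 36.8% and 37.8%, against 49.4% and 49.5% of random positions.

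Targets of YAP and TEAD carried nearby peaks more often than other genes. Of 22 members 16 had a summit within 10 kb in list 1 and 16 in list 2, or 72.7% (exact interval 49.8 to 89.3), against 26.7% and 26.3% of other genes. The odds ratios were 6.97 and 7.12, with adjusted exact p of 3.59e-05 and 3.39e-05 by Fisher's exact test. This excess was not particular to YAP/TEAD targets. Odds ratios were higher in both lists for actin cytoskeleton and adhesion genes (8.66 and 8.86) and in list 1 for activated fibroblast genes (7.50). The other genes were all other protein-coding genes, not only those expressed in these cells. Whether expressed genes as a set show a like excess was not tested. Ccn1, the matricellular protein also known as Cyr61, had a peak on chromosome 3 at 145651277 to 145652329, 1.95 kb from a gene end, that was 28.9-fold over input in list 1 (95% interval 23.7 to 35.0). In list 2 the same site was 25.1-fold over input (20.6 to 30.5). Ankrd1, encoding a stress-responsive ankyrin repeat protein of muscle, had a peak on chromosome 19 at 36118840 to 36120728, 0.25 kb from a gene end, with 101 fragments in each list and folds of 35.0 and 20.2 over local backgrounds of 1.91 and 4.06 fragments. Nt5e, the ecto-5′-nucleotidase CD73, reached 41.9-fold and 48.5-fold. At Ccn2, encoding connective tissue growth factor, the strongest nearby peak of list 1 lay on chromosome 10 at 24589060 to 24589977, 5.99 kb from a gene end (24.9-fold). That of list 2 lay at 24594986 to 24595542, 0.075 kb from a gene end (42.2-fold). Both sites were called in both lists and differed in rank. Their −log10 q, 109.6 in list 1 and 192.1 in list 2, exceeded those of all list-only peaks (at most 80.05 and 89.01).

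Components of the Hippo pathway itself had nearby peaks in 12 of 23 cases in list 1 (odds ratio 2.98, adjusted exact p = 0.0224) and 13 of 23 in list 2 (odds ratio 3.60, adjusted exact p = 0.00786). Lats2, named here after its values were seen, was also a YAP/TEAD target, so the same peak was counted for both gene lists. Among the components with a peak were Vgll3, a TEAD cofactor (23.7-fold and 25.3-fold), Amot, which binds YAP (20.8-fold and 33.8-fold), and Wwc1, also known as Kibra (18.4-fold and 27.9-fold). Tead1 had a weak peak 2.6 kb from a gene end, 7.41-fold over input in list 1 and 5.58-fold in list 2. Inside the Tead1 span there were 8 summits in each list, and the strongest of these was 19.8-fold and 29.7-fold over input. This list no longer passed the threshold with the 5000 strongest peaks per list (adjusted exact p = 0.0564 in both) or with summits within 1 kb (0.684 and 1). Without the block of chromosome 9 that holds Yap1, 12 of 23 members remained in list 2 (odds ratio 3.06, adjusted exact p = 0.0213 by Fisher's exact test). That setting was chosen after the data were seen.

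Genes of fibroblast activation and of the extracellular matrix were the next groups. Among 27 activated fibroblast genes 20 had a nearby peak in list 1 (odds ratio 7.50, adjusted exact p = 4.22e-06) and 19 in list 2 (odds ratio 6.44, adjusted exact p = 1.71e-05). Ddah1, which breaks down an inhibitor of nitric oxide synthase, had folds of 46.9 and 76.2 at a site 7.92 kb from a gene end. The collagen gene Col5a1 had folds of 17.99 and 24.56. Ddah1 and Col5a1 were named for the strength of their peaks. The standard markers of activation Acta2, Postn and Col1a1 were named in any case, and their peaks were weaker, as ranking by strength implies. Acta2, encoding smooth muscle actin, had a peak on chromosome 19 at 34262204 to 34263130 that was 9.74-fold over input in list 1 (95% interval 6.83 to 13.5) and 13.3-fold in list 2 (9.44 to 18.1). Postn, encoding periostin, had folds of 7.81 and 9.54 at a site 0.6 kb from a gene end, and Col1a1 folds of 12.8 and 10.8 at a site 8.06 kb away. Other matrix genes had a nearby peak in 18 of 26 cases in each list (odds ratios 5.97 and 6.11, adjusted exact p = 3.39e-05 in both). In list 2 the same peak was counted for both Col4a1 and Col4a2, named here after their values were seen. Lamb1, a laminin chain, was highest in both lists (43.0-fold and 38.3-fold), and the protease inhibitor Timp2 (23.9-fold and 29.7-fold) and the membrane protease Mmp14 (23.5-fold and 31.4-fold) were among the others. With summits within 1 kb the count was 0 of 26 in each list (adjusted exact p = 0.710 and 0.858).

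**Figure D1:**
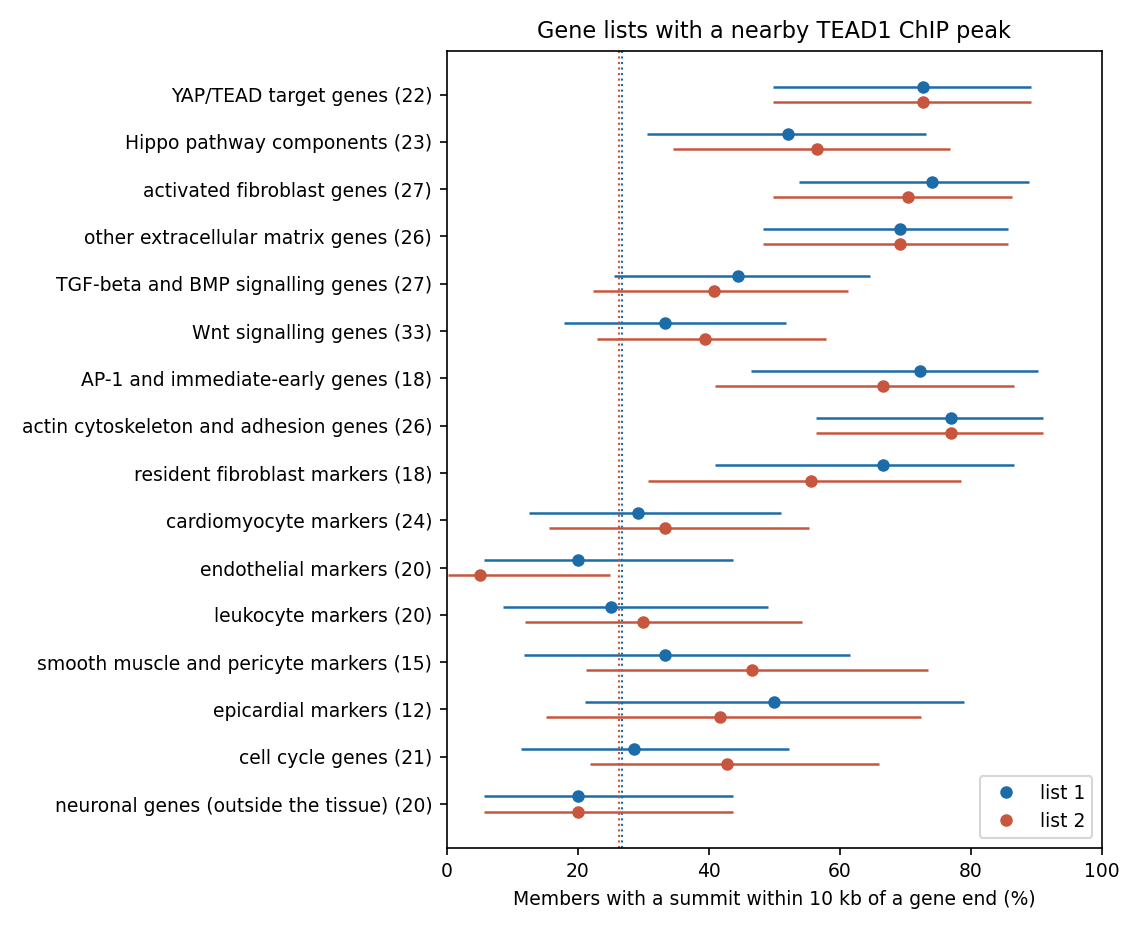
Percentage of the members of each of the 16 gene lists (number of members in brackets) that had a peak summit within 10 kb of an end of the gene, on the x axis, in list 1 (blue) and list 2 (red). Points are the observed percentages, bars the exact 95% intervals, and dotted lines the median percentage of all other genes, near 26.7% and 26.3%; the actin cytoskeleton and adhesion genes stand highest, at 76.9% in both lists.

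Actin cytoskeleton and adhesion genes had the highest share, with 20 of 26 members in each list (odds ratios 8.66 and 8.86, adjusted exact p = 2.20e-06 in both). These odds ratios do not allow for the base pairs near each gene. The binomial test over base pairs does, and it changed the order. There the share of peaks over the share of base pairs was highest for AP-1 and immediate-early genes in list 1 (6.83, actin 6.29). In list 2 it was highest for activated fibroblast genes (6.10, actin 5.92). Other matrix genes had 3.61 and 3.74. Cald1, encoding the actin-binding protein caldesmon, was 29.0-fold and 26.0-fold over input, and the talin gene Tln1 22.24-fold and 30.01-fold. AP-1 and immediate-early genes had a nearby peak in 13 of 18 cases in list 1 (odds ratio 6.73, adjusted exact p = 2.63e-04) and 12 of 18 in list 2 (odds ratio 5.39, adjusted exact p = 0.00124). Ier3 led them (28.6-fold and 41.2-fold, 8.7 and 8.8 kb from a gene end), then the AP-1 subunit gene Fosl2 (18.0-fold and 20.2-fold) and Klf6 (16.3-fold and 18.5-fold). Markers of resident fibroblasts followed with 12 of 18 (odds ratio 5.27, adjusted exact p = 0.00133) and 10 of 18 (odds ratio 3.46, adjusted exact p = 0.0276). Ddr2, a collagen receptor, had a peak 0.03 kb from a gene end with folds of 25.4 and 21.9. Col15a1 had 63 fragments in list 1 and 77 in list 2 and folds of 7.29 and 16.8 over local backgrounds of 7.78 and 3.65 fragments, and Pdgfrl had folds of 8.76 and 10.5. With the 5000 strongest peaks per list the resident fibroblast markers did not pass the threshold (adjusted exact p = 0.285 in both).

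TGF-beta and BMP signalling genes did not pass the threshold after adjustment, with 12 of 27 members in list 1 (odds ratio 2.21, adjusted exact p = 0.0975) and 11 of 27 in list 2 (odds ratio 1.95, adjusted exact p = 0.196). Counting any summit in the gene span as well brought them past it (odds ratios 3.34 and 3.89, adjusted exact p = 0.00406 and 0.00192), as did summits within 50 kb (adjusted exact p = 0.00693 in both). Smad7, the inhibitory Smad, had a peak on chromosome 18 at 75362989 to 75364213, 3.92 kb from a gene end, that was 47.0-fold over input in list 1 (95% interval 39.2 to 55.9) and 33.6-fold in list 2 (28.1 to 39.9), with 127 and 128 fragments over local backgrounds of 1.72 and 2.84. Acvr1, a BMP receptor gene, had folds of 11.7 and 7.95, and Fst, encoding follistatin, folds of 8.81 and 9.18. Wnt signalling genes had 11 of 33 members with a peak in list 1 (odds ratio 1.40, adjusted exact p = 0.600) and 13 of 33 in list 2 (odds ratio 1.84, adjusted exact p = 0.187). Dvl1, a cytoplasmic Wnt transducer, was 53.2-fold and 53.6-fold over input at a site 9.80 kb from a gene end. Gsk3b was 25.5-fold and 26.5-fold at a site 0.08 kb from a gene end, and Tcf7l2 14.96-fold and 14.76-fold.

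No list of another cell type passed the threshold. Cardiomyocyte markers had peaks in 7 and 8 of 24 cases (adjusted exact p = 0.845 and 0.648), with Mb at 5.37-fold and 10.4-fold, Ryr2 at 5.51-fold and 10.8-fold and Nppa at 4.77-fold and 6.27-fold by a peak also counted for Nppb. Endothelial markers had 4 of 20 in list 1 and 1 of 20 in list 2 (adjusted exact p = 0.709 and 0.0810), where Eng alone was found in both (15.1-fold and 13.6-fold) and Pecam1 (6.21-fold) and Plvap (5.14-fold) in list 1. Leukocyte markers had 5 and 6 of 20 (adjusted exact p = 1 and 0.845), with Cd79a at 6.46-fold and 6.98-fold and Cx3cr1 at 3.34-fold and 3.38-fold. Smooth muscle and pericyte markers had 5 and 7 of 15 (adjusted exact p = 0.709 and 0.156). Among these the pericyte gene Rgs5 had a peak 0.26 kb from a gene end that was 20.5-fold and 39.0-fold over input, Notch3 was at 10.4-fold and 10.7-fold, and Lmod1 at 7.71-fold and 10.8-fold. Epicardial markers had 6 and 5 of 12 (adjusted exact p = 0.172 and 0.467), among them the mesothelial gene Msln (20.6-fold and 18.3-fold), Upk3b (8.45-fold and 8.37-fold) and Krt8 (5.79-fold and 9.42-fold). Cell cycle genes had 6 and 9 of 21 (adjusted exact p = 0.845 and 0.202), among them Ccnd2 (11.4-fold and 9.77-fold), Bub1 (9.91-fold and 8.72-fold) and Mki67 (5.87-fold and 11.5-fold). Neuronal genes, chosen as genes outside the tissue, had 4 of 20 in each list (adjusted exact p = 0.709 in both). Eno2 was at 7.05-fold and 10.4-fold, at different sites in the lists. Syn1 was at 6.24-fold and 4.88-fold by a peak also counted for the activated fibroblast gene Timp1, and Grin2b at 5.93-fold in list 2 alone. With summits within 50 kb the threshold was passed by smooth muscle and pericyte markers (adjusted exact p = 0.00699 and 0.00139), cell cycle genes (0.0400 and 0.0139), Wnt genes (0.0470 and 0.0224) and, in list 1, cardiomyocyte markers (0.00464). Within 1 kb it was missed by AP-1 and immediate-early genes (adjusted exact p = 0.0686 and 0.224), resident fibroblast markers (0.234 and 0.517) and, in list 2, actin cytoskeleton and adhesion genes (0.0519).

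**Figure D2:**
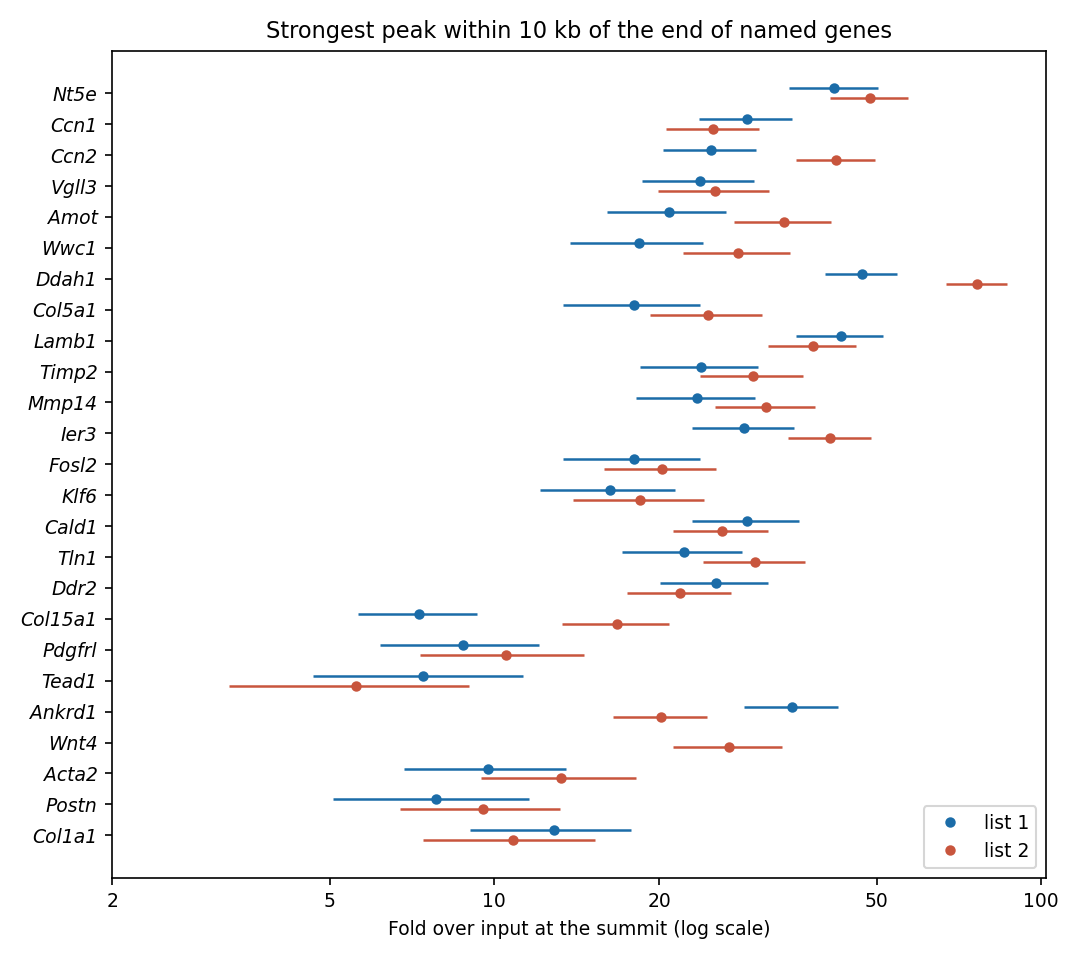
Fold over input (x axis, log scale) of the strongest peak within 10 kb of an end of 25 named genes, in list 1 (blue) and list 2 (red), with exact Poisson 95% intervals of the ChIP fragment number as bars. Of the genes drawn, Ddah1 stands highest in both lists (46.9-fold and 76.2-fold), Col15a1 lowest in list 1 (7.29-fold) and Tead1 lowest in list 2 (5.58-fold), and Wnt4 has a point in list 2 only (26.9-fold). The Ccn2 points of the lists are from different sites, each of which overlapped a peak of the other list.

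The lists were then compared with each other. Of list 1 peaks 15095 overlapped a list 2 peak, or 70.9% (Wilson interval 70.3 to 71.5), and of list 2 peaks 15145 overlapped a list 1 peak, or 71.4% (70.8 to 72.0). Random placement gave a mean of 0.962% and 0.972% and at most 1.18% and 1.16%, with a permutation p of 0.009901, the smallest that 100 placements can give. Overlap rose with strength. In the lowest decile of list 1 by −log10 q 29.4% of peaks were shared, and in the highest decile 99.8%. The same deciles of list 2 had 28.2% and 99.9%.

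**Figure D3:**
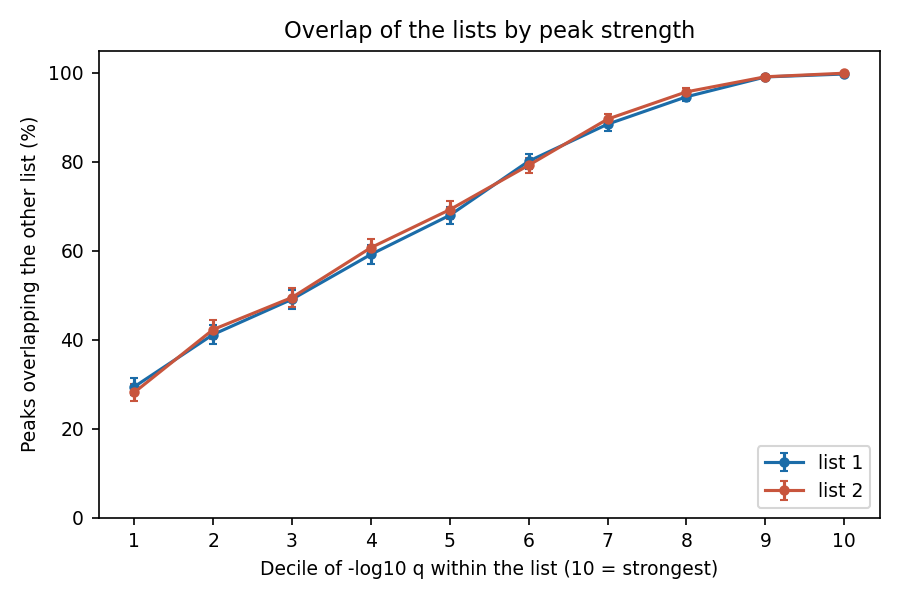
Percentage of peaks that overlapped the other list (y axis) by decile of −log10 q within the list (x axis, 10 the strongest), for list 1 (blue) and list 2 (red), with Wilson 95% intervals as bars. Overlap runs from 29.4% to 99.8% in list 1 and from 28.2% to 99.9% in list 2.

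At the shared sites the folds of the lists moved together. Over 15015 pairs of peaks, Pearson's r of the log2 folds was 0.798 and Spearman's rho 0.729, both across sites, which are not independent replicates. The median log2 ratio of list 2 over list 1 was 0.15 (SD 0.55 across pairs), a ratio of 1.11. A fold at least 2 times as high was seen in list 2 at 873 pairs and in list 1 at 286. With 1 library behind each list, these differences could not be set against a spread between replicates.

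Nearby peaks of the same genes were also mostly shared. Of 21883 protein-coding genes 4552 had a nearby peak in both lists, 1303 in list 1 alone and 1208 in list 2 alone. Members with a peak in one list only were too few to compare most gene lists between the peak lists. An exact McNemar test needs at least 6 such members for an unadjusted p under 0.05, and 1 of the 16 gene lists had them, the cardiomyocyte markers with 3 in list 1 alone and 4 in list 2 alone (exact p = 1). Of the cardiomyocyte markers in list 2 alone, Mybpc3 was counted by a peak also counted for the leukocyte marker Spi1. Among Hippo genes Taok1 had a nearby peak in list 1 alone and Mob1a and Yap1 in list 2 alone. Among Wnt genes Axin2 and Wnt4 had one in list 2 alone. Yap1 lies in the block of chromosome 9 with raised input background. Its nearby list 2 peak was 4.18-fold over input, over a local background of 10.96 fragments. List 1 had 3 summits inside the Yap1 span, up to 13.6-fold, but none within 10 kb of a gene end. These names beyond Wnt4 were chosen after their values were seen.

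The strongest peaks in one list only included a gene fixed beforehand. Wnt4, encoding a secreted Wnt ligand, had a list 2 peak on chromosome 4 at 137275699 to 137276360, 1.44 kb from a gene end, that was 26.9-fold over input (95% interval 21.2 to 33.5) with 76 fragments. The nearest list 1 summit lay 63.1 kb away. Wnt4 was also the nearest protein-coding gene, at 77.0 kb, to a list 1 peak at 137200259 to 137200778 (17.2-fold), from which the nearest list 2 summit lay 75.6 kb away. The other leading peaks of list 1 alone lay near Malt1 (25.7-fold, 69 fragments), inside Ano2 (19.1-fold), inside AW554918 (16.9-fold) and near Tmem259 (17.6-fold). The Tmem259 peak had a list 2 summit 1.502 kb away, so that locus was not without list 2 peaks. For Malt1, Ano2 and AW554918 the nearest list 2 summit lay 46.05, 60.75 and 96.34 kb away. Other leading peaks of list 2 alone lay near Epha2, an ephrin receptor gene (17.4-fold, 49 fragments), and inside the TEAD cofactor gene Vgll4 (17.4-fold). Further ones lay 94.8 kb from Igfbp7 (15.5-fold) and inside Uvrag (15.7-fold). From these peaks of list 2 the nearest list 1 summit lay 11.45 to 44.8 kb away. A site absent from a list was one that did not pass the authors' calling threshold there, and its signal below that threshold was not analysed here.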

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

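All tests in this part were chosen after the results had been seen. The lists also carry the local background that the peak caller took from the input, recovered from the fold and p of each peak, and no planned comparison tested it. Its values stood above the genome-wide floor in a stretch of chromosome 9 and on some whole chromosomes.

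On chromosome 9, between 5812677 and 8836955, a run of 80 consecutive list 2 peaks had a background of at least 3 times the floor, while the longest such run on any other chromosome was 2 peaks. The median background in this block of 3.02 Mb was 2.71 times the floor in list 1 (41 peaks, quartiles 2.48 and 3.12) and 5.87 times in list 2 (80 peaks, quartiles 5.36 and 6.96), and the block holds 21 protein-coding genes, among them Yap1, Birc2, Birc3, Pdgfd and a group of matrix metalloproteinase genes. List 1 alone, by its longest run of peaks with at least 1.5 times the floor (42 peaks, against at most 14 on any other chromosome), gave nearly the same stretch, 5842031 to 8837103. Piled-up reads of repeated sequence, which would give like values in both lists, are argued against there by the ratio of the medians, 2.16 (95% bootstrap interval 1.93 to 2.27). The interval draws peaks as if independent. With 1 input behind each list, it does not cover the error between inputs. Extra DNA copies of this region in the cells, in more copies or in more cells behind list 2, may account for the raised background. The 17 list 2 peaks flanking the stretch found from list 1 had a median of 1 time the floor, though an abrupt end does not tell extra copies from a domain of open chromatin. This stays a hypothesis, such a domain was not tested and stays open too, and whether it goes with TEAD1 overexpression was not tested, since the lists are not tied to the conditions.

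Whole chromosomes differed as well. On chromosome 15, 94.7% of list 1 peaks and 95.8% of list 2 peaks had a background above the floor, with a median of 1.504 times the floor in both lists, against a median of 1 on chromosomes 5, 6, 7, 9, 13, 18 and X. Spearman's rho between the share above the floor and genes per Mb over 20 chromosomes was at most 0.122 (permutation p = 0.608). With 20 chromosomes this cannot exclude a moderate relation with gene density. Sampling noise of the input is argued against by a rho of 0.970 between the lists (permutation p = 1.00e-05, the smallest that 100000 permutations can give). Extra copies of whole chromosomes may account for it, since the share rose with peaks per Mb (rho of 0.767 in list 1 and 0.755 in list 2, adjusted permutation p = 4.00e-04 in both, over 5 relations), and Pearson's r without the 2 farthest chromosomes was 0.732 and 0.677. A chromosome-wide difference in open chromatin or base composition stays open, as it could raise peaks and background together and no genome sequence was used. No biological explanation from the design was tested.

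Strong peaks, those with at least 30 fragments at the summit, were found in one list only 67 times among 5420 in list 1 and 146 times among 6801 in list 2. Of those in list 2, 27 lay in the block of chromosome 9 and 119 elsewhere. The cut is on fragments, not on fold. In the block the median list 2 background was 5.87 times the floor, so 30 fragments there stood for a lower fold than over the floor. No explanation was tested, because each list rests on 1 library and signal below the calling threshold was not analysed here.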

How the results depend on the processing

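The settings that leave out the chromosome 9 block, leave out peaks with a background of at least 2 times the floor, or shift whole chromosomes were chosen after seeing the data. The others were planned. No paired analysis was possible because each group has 1 library. The TEAD motif tests and their alternatives were not run, for want of a genome sequence. Taking rows as deposited changed no value, since no interval occurred more than once. Taking all sequences was run for the numbers of peaks only and left them as they were.

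The 5000 strongest peaks per list is a fixed number, 5000 in place of 21285 and 21218. Overlap between the lists stayed above each of 20 random placements under every setting run, from 62.0% to 77.9% in list 1 and from 62.2% to 78.0% in list 2. The share within 1 kb of a gene end stayed above random positions under a −log10 q of at least 5 and with the 5000 strongest peaks, where it was lowest (3.80% and 3.74%, odds ratios 1.27 and 1.21), and so did the shares with other distances and all annotated genes.

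The number of gene lists past the threshold, 7 in each peak list, fell to 3 in list 1 and 2 in list 2 with summits within 1 kb and rose to 12 and 11 within 50 kb. YAP/TEAD targets and activated fibroblast genes passed in both lists within 1 kb. In the binomial test, the ratio of the share of peaks to the share of base pairs took the place of the odds ratio, and it brought TGF-beta and BMP genes past the threshold (2.67 in list 1, 2.07 in list 2), and in list 2 smooth muscle and pericyte markers (2.27). Over 256 such values (16 lists, both peak lists, 8 settings, rows as deposited left out), 203 kept their direction and side of the threshold, 13 lost significance, 14 gained it and 28 crossed 1, and 2 of those that crossed 1 are also among the 13. Between the peak lists, at most 1 of the 16 gene lists had enough discordant members for an exact McNemar test to pass under any setting run, so these tests say nothing about stability.

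Of the 28 values that crossed 1, 26 belonged to lists that had not passed, and 0 passed the threshold afterwards. In 9 of the 28 no member had a nearby peak, and the 0.5 added to each cell sets the ratio. For the others the cause was not tested. Within 1 kb the values that crossed were other extracellular matrix genes, which had passed (0 of 26 members in each list, 0.323 in list 1, 0.345 in list 2), epicardial markers (0.686 and 0.7325) and, in list 1, leukocyte markers (3.44), cell cycle genes (0.399) and neuronal genes (1.32). Within 50 kb they were leukocyte markers in list 1 (1.365) and endothelial markers in list 2 (1.09). With summits in the gene span they were, in list 1, endothelial (1.65), leukocyte (1.11), cell cycle (0.839) and neuronal genes (1.11) and, in list 2, leukocyte (0.894) and neuronal genes (1.11). With the 5000 strongest peaks they were cardiomyocyte markers (0.265 and 0.268), cell cycle genes (0.949 and 0.306) and, in list 2, TGF-beta and BMP (0.744), endothelial (1.01), leukocyte (0.321) and neuronal genes (1.01). With a −log10 q of at least 5 they were cardiomyocyte markers in list 1 (0.592) and leukocyte markers in list 2 (0.940). In the binomial test they were leukocyte (1.198) and neuronal genes (1.17) in list 1, and without peaks with a raised background leukocyte markers in list 1 (1.04).

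Spearman's rho of the folds at shared sites moved from 0.729 to 0.706 with a −log10 q of at least 5, 0.668 with the 5000 strongest peaks, 0.744 with overlap of 50% of both peaks, and 0.755 without peaks with a background of at least 2 times the floor. The cause was not tested. With 8 fragments at the lowest summits, absence of a weak peak from a list was not read as a difference. Whether depth set which weak peaks were called was not tested.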

Other observations

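Some of the strongest peaks lay far from the ends of protein-coding genes and were chosen here after their values were seen, and distances to other annotated genes were not taken. A site on chromosome 10 at 17012093 to 17013324, 710.5 kb from its nearest protein-coding gene Cited2, was 93.4-fold over input in list 1 and 122.7-fold in list 2. A site on chromosome 15 at 62327765 to 62329867 lay 338.2 kb from Myc, the nearest protein-coding gene, with folds of 59.7 and 100.8. Inside Pard3, which encodes a cell polarity protein, a site on chromosome 8 at 127256910 to 127258254, 194.3 kb from a gene end, had folds of 95.5 and 146.2. The most summits, counted inside a protein-coding gene's span or within 10 kb of it, were held by Lpp in list 1 (27, for a span of 599.2 kb) and by Lrmda in list 2 (28, for 1036.6 kb), both long genes. Per 100 kb of the span with 10 kb on each side these were 4.36 and 2.65. Among the 12 genes per list with the most summits Vmp1 had the highest density, 20 in list 2 for a span of 99.98 kb. Counted over the span with 10 kb on each side, this was 16.7 per 100 kb. Ext1, for heparan sulfate synthesis, came next with 6.71 in list 1 and 7.05 in list 2. Whether such counts exceed what gene length gives was not tested.

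The highest fold of list 1, 149.6, belonged to a peak on chromosome 17 at 4626165 to 4626598, 368.0 kb from its nearest protein-coding gene Arid1b, with 459 fragments. In list 2 the site had 56 fragments and a fold of 6.86. Its local background was 2.07 fragments in list 1 and 7.31 in list 2.

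The lists also contain sites with a high −log10 q and almost no enrichment. A peak on chromosome 2 at 98666742 to 98667199 had a fold of 1.26 and a −log10 q of 495.6 in list 1, and 1.58 and 1933.5 in list 2. A peak on chromosome 9 at 3024061 to 3024552 had 1.35 and 460.1 in list 1, and 1.70 and 1481.4 in list 2. These are the 2 peaks per list whose fragment number did not come out whole, so no background is given for them.

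Inside the Yap1 span there were 3 summits in list 1 and 8 in list 2, with a highest fold of 13.6 and 25.8. Pdgfd, in the same block of chromosome 9 and encoding a platelet-derived growth factor, held 10 and 20 summits with a highest fold of 37.5 and 49.5. The site named above for Ddi1 is among them.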
